A study of Drosophila melanogaster with 2 samples.

How the data were processed

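Total RNA came from pools of 40 dissected midguts of germ-free Drosophila larvae, 1 pool kept on sterile PBS and 1 pool monoassociated with L. plantarum for 4 h. Per the labels' protocols, RNA was extracted with TRIzol, cleaned on RNeasy columns, and labelled with biotin by the Affymetrix double-strand whole-transcript method. Each pool was hybridised to 1 array, the DroGene 1.0 design per the file headers. Samples were grouped by their source labels, with 1 array per group.

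The deposited table holds an intensity per transcript cluster and array, made by the authors with RMA (robust multi-array average, a background correction, normalisation across arrays and probe summary), per the submitters' processing notes. The RMA software, its version and the level of summarisation are not given in the sources used here. The values ran from 2.34 to 13574 on the PBS array and from 1.78 to 13899 on the L. plantarum array, so the intensity scale of the deposited values is linear. The analysis plan had assumed log2 values, and log2 of the intensities was therefore taken first. A deposited signed fold score per feature was checked against the ratio of the intensities, with a largest gap of 3.86e-09, and was not used otherwise. The second deposited table held the same intensity values, with 0 features differing. RMA makes the distributions of the arrays alike, so a shift shared by most genes cannot be seen, and it tends to compress differences of dim features.

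Of 16322 features, 14810 carried a gene symbol and 1512 did not. Symbols were updated through a table of the current release 6 annotation, by RefSeq accession for 3390 features, by symbol for 8749, by locus tag for 1751 and by synonym for 689, and the name in the deposited table was kept for 231. Coordinates are those of the deposited annotation, release 5, and span the transcript cluster; exon positions were not used. For 283 genes with several features, the feature with the higher mean of the arrays was kept, which gave 14395 genes. At 0 of these genes did features lie on opposite sides of zero by 0.5 or more. The floor was the 95th percentile of the mean log2 value of 58 odorant receptor genes, which midgut is not thought to express, and equalled 5.29 (intensity 39.1). A gene was kept if its higher array exceeded the floor, which held for 7803 genes (54.2%), 7084 on both arrays and 719 on 1 array. Where a gene was at or below the floor on 1 array, its fold was computed against the floor and is given as at least that fold.

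With 1 array per group no test of the treatment could be made, and the number of arrays limits the precision. Genes were counted as different at 2-fold or more. For 41 gene lists the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins with a fixed seed. A list outside the central 95% was said to stand apart, as a description of the arrays. Lists with fewer than 3 members above the floor were not placed. The lists, the counts and the rule for naming genes were fixed before the data were examined. The rule named the 12 highest and 12 lowest genes, up to 4 members with the largest differences from each list that stood apart or was a planned comparison, and all Nrf2 regulators and reference genes. Genes named outside the rule serve as examples and were chosen after their values were seen; these are members given for lists that did not stand apart and the genes named in the closing part.

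The lists covered Nrf2 regulators, reported CncC targets, detoxification enzymes, immunity, signalling, digestion, stress, ribosomes, respiration and markers of midgut cell types and neighbouring tissues. Symbol families with 8 or more members above the floor were scanned in the same way (47 families, 2.35 expected outside by chance if genes varied independently). Runs of 7 neighbouring genes were compared with 1000 permuted gene orders. A proteasome list, a second list of Malpighian tubule genes and a split by gene class were added after the data had been seen.

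Alternative settings chosen in advance were the second deposited table, no floor, a floor on both arrays, centring on the median difference, removal of a loess curve against mean intensity (fraction 0.3), the mean of all features of a gene, thresholds of 1.5-fold and 3-fold, and unmatched random lists. Protein-coding genes only and dim values set to the floor were added after seeing the data. An alternative that leaves out cross-hybridising probe sets by their name endings was not run, because the feature names have no such endings. The counting and list steps were tested on simulated data for L. plantarum against PBS over 7803 genes, with an assumed noise SD of 0.4 for every gene. With 1 array per group the array noise could not be measured, so the rates below hold for that SD only. Of 200 planted 4-fold differences, 99.5% were recovered, and 92 of 7603 unchanged genes passed 2-fold. Of 200 random lists of 20 genes, 5% stood apart, and of lists shifted by 0.4, 93.5% did. Features without a gene name were left out of the gene counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.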

Results

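Gene expression was measured in the midgut of germ-free 3rd instar larvae of Drosophila melanogaster, in animals given sterile phosphate-buffered saline (PBS) or monoassociated with Lactobacillus plantarum, a gut-resident lactic acid bacterium, for 4 h. RNA from a pool of 40 dissected midguts per group was hybridised to 1 Affymetrix DroGene 1.0 whole-transcript array each, so the comparison rests on 1 array per group, has no replicate check, and allows no p-value, and the number of arrays limits the precision. The deposited values were RMA intensities on a linear scale, with medians of 40.2 (PBS) and 40.9 (L. plantarum) over 16322 features. After 1 feature was kept per gene, 7803 of 14395 genes lay above a floor of intensity 39.1 set by odorant receptor genes. All differences below are L. plantarum minus PBS on the log2 scale unless a fold is given.

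The comparison asked which midgut transcripts differed after the bacterium was swallowed, and the series title ties the question to the Nrf2 pathway, whose fly form pairs the transcription factor cnc with its inhibitor Keap1. The antimicrobial peptide gene AttD and the immune regulator pirk, an inhibitor of the IMD pathway, were among the most elevated transcripts in the L. plantarum pool, while the salivary glue genes Sgs8 and Sgs7 were the furthest reduced. Reported targets of the Nrf2 homologue were split evenly, with 9 higher and 10 lower and none reaching 2-fold. Genes of the IMD and JAK-STAT pathways lay higher as groups, while digestive peptidases lay inside the range of other genes of like expression. Marker genes of other tissues also differed between the pools. Malpighian tubule markers above the floor were higher after L. plantarum, and markers of salivary gland and fat body were lower. Of 13 cuticle markers only 3 were above the floor, and 2 of these, Lcp1 and Lcp4, were lower.

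In all, 128 genes were 2-fold or more higher and 92 were 2-fold or more lower after L. plantarum, together 2.82% of the genes above the floor. The median difference was −0.04, 90% of genes fell between −0.65 and 0.69, and Pearson's r between the arrays was 0.964 across genes, which are not independent replicates. Of the higher genes, 46 were at or below the floor on the PBS array. Of the lower genes, 29 were at or below it on the L. plantarum array. Folds of these genes against the floor are lower bounds, but the counts use their measured values. With dim values set to the floor, 98 genes were 2-fold or more higher and 74 were 2-fold or more lower.

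AttD, on chromosome arm 3R from 13450990 to 13451808 in release 5 coordinates (transcript cluster 18186810), went from an intensity of 22.7 to 184, at least 4.70-fold higher. The gene pirk, on 2R from 17548472 to 17549749 (transcript cluster 18161522), had an intensity of 450 with PBS and 2481 with L. plantarum, 5.51-fold higher. The uncharacterised genes CG13075 and CG16762 were 7.48-fold and 5.77-fold higher, and CG13324 was higher by 2.32. Uro, the urate oxidase gene of Malpighian tubules, was 4.89-fold higher, with intensities of 188 and 918. Cyp6a18, a cytochrome P450, was at least 5.07-fold higher and the calcium-binding protein gene Scp2 at least 4.53-fold higher. CG34026 (2.23), CG14302 (2.20) and salt (2.06) followed, and CG34043 was only at least 1.05-fold higher because its L. plantarum value lay just above the floor.

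The lower end was led by glue protein genes of the larval salivary gland. Sgs8, on 3L from 11502067 to 11502494 (transcript cluster 18174168), had intensities of 2363 with PBS and 164 with L. plantarum, 14.4-fold lower. Its neighbour Sgs7, on 3L from 11502961 to 11503347, was 10.8-fold lower, from 754 to 69.9. On 3R, Sgs5 was at least 5.14-fold lower and the adjacent Sgs5bis at least 2.73-fold lower, while CG7606, next to them, was at least 1.24-fold lower. The microRNA stem loop mir-4985 was at least 5.71-fold lower. CG12310 (−2.08), Ance-4 (−1.96), a gene of the angiotensin-converting enzyme family, and CG13012 (−1.72) were measured above the floor on both arrays. CG32249 was at least 3.17-fold lower, CG4962 at least 2.28-fold lower and BomS6, a secreted immune peptide of the Bomanin family, at least 1.55-fold lower.

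**Figure D1:**
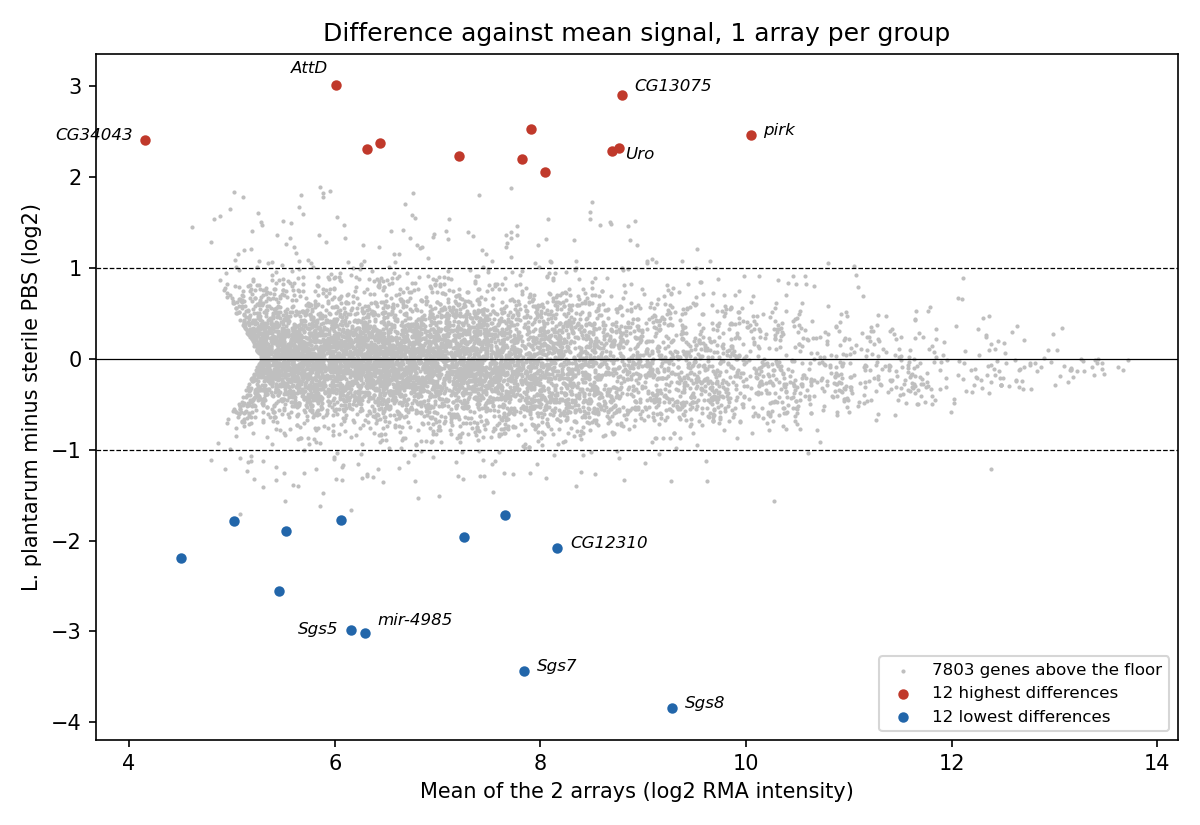
Log2 difference (L. plantarum minus sterile PBS, vertical axis) against the mean log2 RMA intensity of the 2 arrays (horizontal axis) for the 7803 genes above the floor, with the 12 highest genes in red, the 12 lowest in blue and dashed lines at 2-fold. Most genes sit between −0.65 and 0.69, whereas CG13075 (2.90), pirk (2.46) and AttD (at least 4.70-fold higher, drawn at its measured value) stand out above and Sgs8 (−3.85) and Sgs7 (−3.43) below.

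Among the Nrf2 pathway regulators, Keap1 (−0.37), maf-S (−0.31) and cnc (−0.12) were lower and ref(2)P, the fly p62 homologue, was higher (0.57). The 4 genes had a median of −0.21, the 24.95 percentile of random lists matched on expression. Of 19 reported CncC target genes above the floor, GstD4 (0.82), ref(2)P (0.57) and Gclc (0.55), the catalytic subunit of glutamate-cysteine ligase, were highest and Jheh2 (−0.50), a juvenile hormone epoxide hydrolase, was lowest. The list median was −0.02, the 74.4 percentile, inside the range of −0.29 to 0.14 that held the central 95% of random lists, and its sign turned when the arrays were centred (0.01) or an intensity trend was removed (0.07). The 29 glutathione S-transferases divided into 14 higher and 15 lower, with a median of −0.01 (68.8 percentile) that turned sign under the same settings (0.03 and 0.07). GstZ1 was the only member past 2-fold (1.47), followed by GstE10 (0.91), and GstE8 was lower (−0.82).

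Cytochrome P450s, UDP-glycosyltransferases and antioxidant enzymes lay within the range of random lists, while metallothioneins did not. Of 53 cytochrome P450s, 22 were higher and 31 lower, with a median of −0.09 (32.0 percentile). Beside Cyp6a18, the P450s past 2-fold were Cyp4p1 (1.33), Cyp4ac3 (1.11) and Cyp4p2 (1.04) above and Cyp304a1 (−1.47) below, named after their values were seen. UDP-glycosyltransferases had 12 of 21 members higher and a median of 0.10 (89.5 percentile). Among 17 antioxidant enzymes, 12 were lower and the median was −0.12 (40.1 percentile). The catalase-related gene Irc (−1.27), also named after its value was seen, was the only antioxidant enzyme past 2-fold. Metallothioneins lay below random lists, with a median of −0.55 (1.03 percentile). MtnD (−1.16), MtnB (−0.67) and MtnE (−0.44) were lower and MtnA (0.35) was higher.

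The list of IMD pathway genes and peptidoglycan recognition proteins (PGRPs) stood above random lists, with 13 of 19 members higher, 3 of them past 2-fold, and a median of 0.24 (99.1 percentile). Those 3 were pirk (2.46), PGRP-LF (1.33), a receptor-like inhibitor of the pathway, and PGRP-SC1b (1.06), an amidase that cleaves peptidoglycan. Fadd was higher by 0.59. Lower values were found for 6 members, among them Diap2 (−0.43), PGRP-SC2 (−0.37), Tab2 (−0.23), Dredd (−0.17) and imd (−0.13). The antimicrobial peptides went both ways, with 6 of 10 higher and a median of 0.19 (92.0 percentile). AttD was at least 4.70-fold higher and DptA was higher by 0.89, while Drsl3 (−0.93), Mtk (−0.92) and DptB (−0.90) were lower. Over the 7 peptides above the floor on both arrays, which leaves AttD out, the median turned to −0.59, the 0.04 percentile, a filter that itself removes genes dim on the PBS array. Fat body markers, from a tissue that also makes these peptides, were lower in the same pool, with a median of −0.58. All 6 JAK-STAT genes were higher, with a median of 0.53 (99.7 percentile), or 0.34 (98.4 percentile) with dim values set to the floor. The cytokine genes upd2 (at least 1.23-fold higher) and upd3 (0.66), the feedback inhibitor Socs36E (0.72) and Stat92E (0.39) were members. Lysozymes had a median of −0.06 (48.3 percentile) over 3 genes, which turned to 0.04 once an intensity trend was removed. In the same L. plantarum pool the 4 Malpighian tubule markers above the floor were higher, with a median of 0.70, beside these immune groups.

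Of the digestive genes, 13 of 15 Jonah serine peptidases were lower, with a median of −0.18 (25.2 percentile). Jon99Fi (−1.25) and Jon99Fii (−1.01) were lower by 2-fold or more, Jon99Ci was lower by less (−0.77), and the abundant Jon65Ai went from 7829 to 6211 (−0.33). Trypsins (9 of 12 lower, median −0.15, 36.5 percentile) and maltases and amylases (9 of 11 lower, −0.15, 31.4 percentile) were placed similarly. Lipid and sterol handling genes had 14 of 18 members lower and a median of −0.23 (9.26 percentile). Vacuolar ATPase subunits, which acidify the midgut lumen and organelles, had 11 of 19 members higher and a small median of 0.11 that lay above random lists (97.9 percentile). VhaM9.7-b (0.53), Vha68-2 (0.42), Vha26 (0.38) and VhaSFD (0.35) were the largest differences. That list fell back inside the range of random lists when these were not matched on expression (89.0 percentile).

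Signalling, stress and housekeeping lists lay inside the range of random lists, apart from changes of setting named here. The insulin and TOR list had a median of 0.20 (95.9 percentile, 14 genes), and was at the 97.65 percentile, outside the range, after removal of an intensity trend. Medians were 0.27 for EGFR ligands and targets (94.6 percentile, 6 of 6 higher), 0.17 for heat shock proteins (92.5 percentile, 14 genes; 0.11 with dim values set to the floor) and 0.14 for the unfolded protein response (93.6 percentile, 11 genes). Ribosomal proteins were lower in 64 of 84 cases, with a median of −0.19 (2.71 percentile), and lay below the range without a floor (1.13 percentile), with unmatched random lists (0.06 percentile) and among protein-coding genes (0.775 percentile). Mitochondrial respiration genes had a median of −0.05 (65.2 percentile), which turned to 0.03 once an intensity trend was removed. Medians were 0.18 for the peritrophic matrix and mucins (90.3 percentile), −0.07 for epithelial junctions (42.9 percentile), −0.12 for the ecdysone response (19.3 percentile), which turned to 0.02 without a floor, and −0.01 for the circadian clock (49.99 percentile), which turned to 0.03 after centring and 0.01 without the intensity trend. The 11 reference genes ranged from −0.41 (Gapdh2) to 0.48 (eEF1alpha1), with a median of −0.04 that turned to 0.06 without the intensity trend. Act5C (0.10), alphaTub84B (0.03), betaTub56D (0.05), eIF4A (−0.04), Gapdh1 (−0.07), SdhA (−0.09), Polr2B (−0.15), RpL32 (−0.24) and Tbp (0.28) lay between.

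Markers of tissues next to the midgut included the widest list differences, those of salivary gland, cuticle and Malpighian tubule. Of 10 salivary gland genes, 6 were below the floor on both arrays. The other 4, Sgs8, Sgs7, Sgs5 and Sgs3 (at least 1.35-fold lower), were all lower, with a median of −3.21, below every random list drawn, and −2.90 with dim values set to the floor. Fat body genes had 6 of 7 members lower and a median of −0.58 (0.08 percentile), including Lsp2 (−1.22), from 8147 to 3505, Fbp1 (−0.89), Fbp2 (−0.71) and Lsp1beta (−0.58). Of 13 cuticle genes, only 3 were above the floor. Their median was −1.06 (0.055 percentile), with Lcp1 at −1.35, Lcp4 at −1.06 and ple at 0.00, so the placement rests on Lcp1 and Lcp4. Malpighian tubule markers above the floor were higher in 4 of 4 cases, with a median of 0.70 (99.8 percentile). These were Uro (2.29), Irk3 (0.90), ZnT35C (0.49) and Lkr (0.30). CapaR, also on that list, was below the floor on both arrays, with intensities of 19.6 with PBS and 16.4 with L. plantarum. Copper cell and midgut region genes had 7 of 8 members higher and a median of 0.32 (97.6 percentile), among them otp (at least 1.08-fold higher), cad (0.50), lab (0.36) and GATAe (0.35). That list was inside the range of random lists (95.9 percentile) when both arrays had to exceed the floor.

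Markers of other midgut and adjoining cell types did not stand apart. Medians were 0.16 for midgut progenitors (81.8 percentile), which turned to −0.04 without a floor, 0.11 for enteroendocrine cells (80.9 percentile), 0.13 for muscle (91.2 percentile), 0.31 for trachea (94.4 percentile) and −0.33 for haemocytes (5.61 percentile). The haemocyte placement includes vkg (−0.04), a feature that the deposited annotation names veg and places on 2R. That match of names is uncertain, and so is the placement of the list. Fewer than 3 members were above the floor for ROS-producing oxidases (Duox, −0.19), Turandot stress genes (TotA, −0.26, and TotM, at least 1.02-fold higher), testis genes (betaTub85D, at least 1.12-fold lower) and neuronal genes, where the count was 0. Of 37 lists that could be placed among random lists, 5 lay above and 4 below the central 95%, where 1.85 would lie outside by chance if genes varied independently. Some lists share members, such as Keap1 and Gclc, and some hold neighbouring genes, such as Sgs7 and Sgs8, so more could lie outside by chance. These placements describe the 2 arrays and do not test the treatment.

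**Figure D2:**
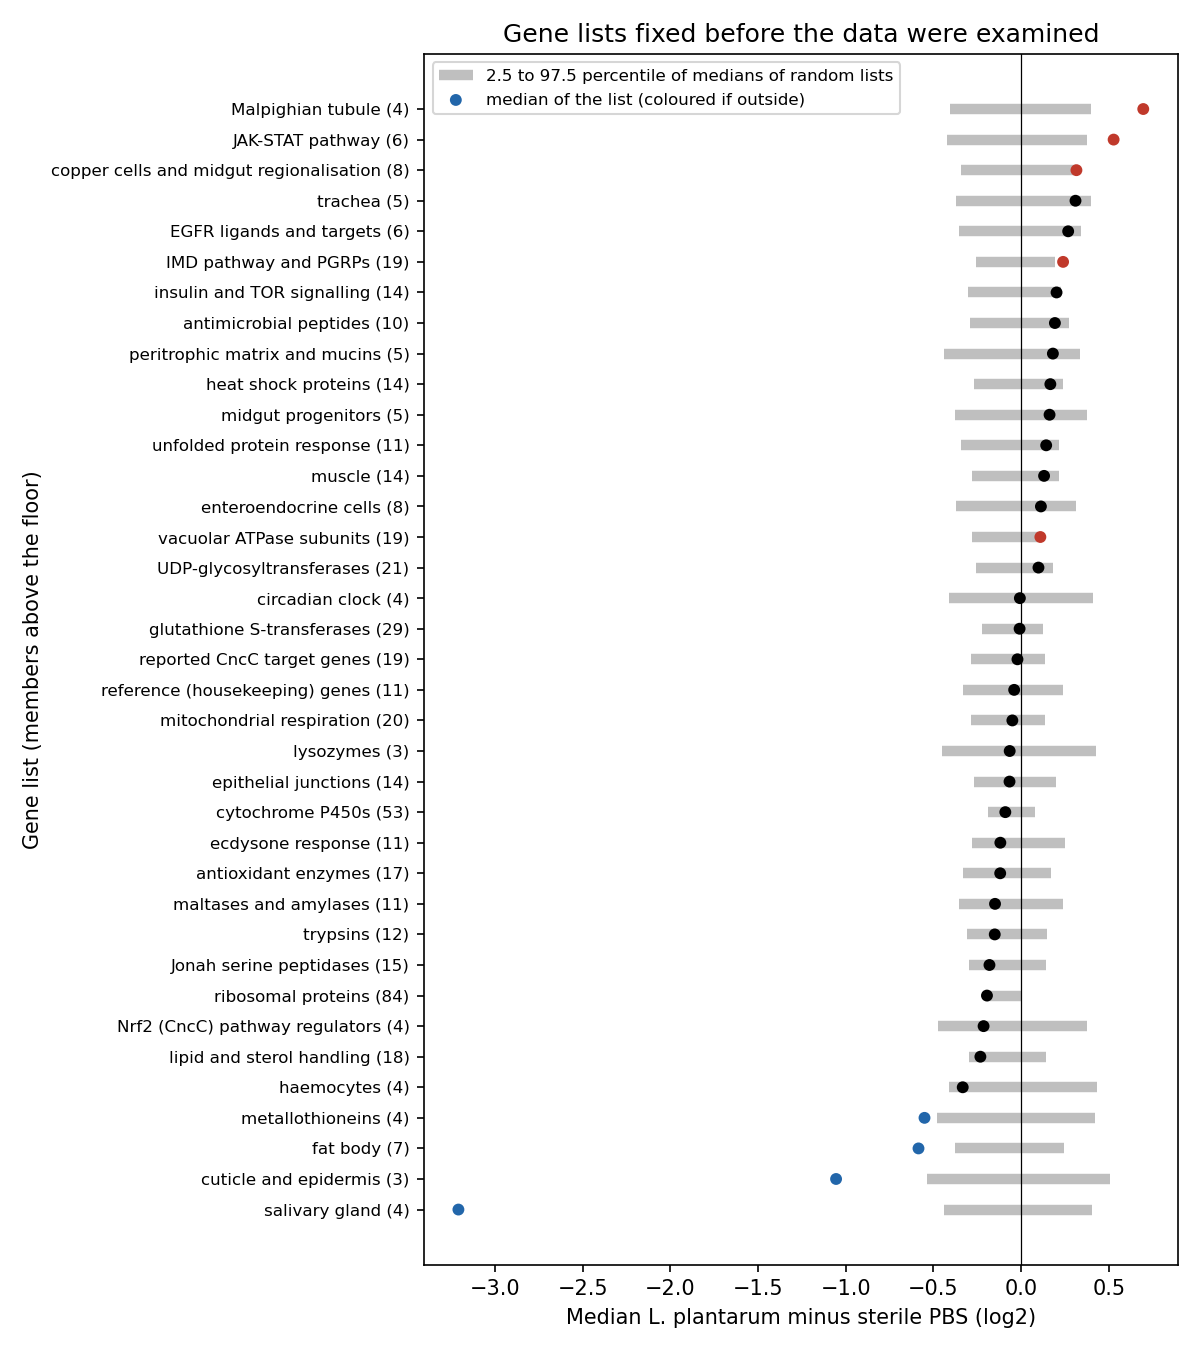
Median log2 difference (L. plantarum minus sterile PBS, horizontal axis) of each gene list, with the number of members above the floor in brackets, as points over grey bars for the central 95% of medians of matched random lists. Red points lie above the bar (for example JAK-STAT pathway, 0.53) and blue points below it (for example salivary gland, −3.21), while CncC targets (−0.02) and glutathione S-transferases (−0.01) lie near 0.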

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

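The count of features without a gene name was chosen only after the values had been seen. The gene comparisons leave these features out, and 632 of them lay above the floor with values not shared with a named gene. Among them 9 were 2-fold or more higher after L. plantarum than in the PBS control and 39 were 2-fold or more lower, but with dim values set to the floor 4 and 24 remained past 2-fold. Transcript cluster 18194905 had an intensity of 40.8 with PBS and 155 with L. plantarum, 3.81-fold higher, and transcript cluster 18194903 was at least 3.58-fold higher, from 29.6 to 140. Several of the lower features carry identical values, so they are fewer separate measurements than their number. A further 85 unnamed features repeat the values of a named feature. No sequence was matched to these features here, and neither a technical nor a biological explanation was tested.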

How the results depend on the processing

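Restriction to protein-coding genes and dim values set to the floor were chosen after seeing the data; the other settings were planned. The count of higher genes was 128 as reported and 138 without a floor, 140 after centring, 142 after loess, 122 for protein-coding genes and 98 with dim values set to the floor. The count of lower genes was 92 as reported and 102, 85, 85, 69 and 74 under those settings. With both arrays above the floor there were 82 higher and 63 lower genes, a loss that follows from construction, since 46 higher and 29 lower genes were dim on 1 array. At 1.5-fold there were 572 higher and 562 lower genes, and at 3-fold 30 and 15, again by construction. The antimicrobial peptide median turned from 0.19 to −0.59 with both arrays above the floor, because AttD, CecB and Drsl1 left the list. Of the other lists, 285 of their values under alternatives stayed on the same side of the random range and 10 did not: 5 moved outside it and 5 back inside. Ribosomal proteins moved below it without a floor (1.13 percentile), with unmatched random lists (0.06 percentile) and among protein-coding genes (0.78 percentile), lipid handling without a floor (−0.31) and insulin and TOR genes above it after loess (0.27). Vacuolar ATPase subunits moved inside it in 3 settings (0.02 without a floor) and copper cell genes in 2 (0.28 with both arrays above the floor). The cause of these moves was not tested. With dim values set to the floor, the difference of every named gene dim on 1 array shrank. The 7 that moved furthest were AttD (to 2.23), BomS6 (to −0.63), CG34043 (to 0.08), CG4962 (to −1.19), CG7606 (to −0.31), Sgs5 (to −2.36) and Sgs5bis (to −1.45). Others shrank by less, among them upd2 (0.81 as measured, at least 1.23-fold against the floor) and otp (0.58, at least 1.08-fold). The salivary gland list has no value with both arrays above the floor. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Signal over the floor limits what can be said of the 719 genes measured on 1 array.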

Other observations

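The proteasome list, the second list of tubule genes, the gene classes, the runs of neighbouring genes and the tests of explanations, with dim values set to the floor among them, were chosen only after the results had been seen, while the scan of symbol families was planned. Genes of protein turnover and folding lay lower after L. plantarum. Of 31 proteasome genes, 30 were lower, none by 2-fold, with a median of −0.33 (0.48 percentile of matched random lists). Rpt6 (−0.87), a base ATPase, and the core subunits Prosalpha4 (−0.74) and Prosbeta5 (−0.59) were among them, and Rpt5 (0.11) was the exception. All 8 genes of the CCT family, which form a cytosolic chaperonin, were lower, with a median of −0.42 (2.49 percentile), CCT3 at −0.60 and CCT1 at −0.57. Neprilysin-like genes (Nepl) were lower in 9 of 10 cases, with a median of −0.50 (0.08 percentile), including Nepl15 (−0.80), but 6 of them were dim on 1 array and the median was −0.17 (1.16 percentile) with dim values set to the floor.

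The Rab family of small GTPases and their partners lay above random lists, with 17 of 28 members higher and a median of 0.19 (99.2 percentile). Other families of membrane traffic did not, with Tango at −0.30 (7.44 percentile), Vps at −0.09 (33.1 percentile), Sec at −0.05 (51.5 percentile) and Syx at 0.08 (79.3 percentile). Rab39 (0.77), Rab7 (0.60) and Rab5 (0.54) are examples from the first. The vacuolar ATPase family, scanned again by its symbols, lay at the 98.3 percentile. It had 19 genes and a median of 0.11, as did the vacuolar ATPase list, so it is not a separate result. On 3R, from 21095953 to 21148473 in release 5 coordinates, 13 of 16 neighbouring genes of the ecdysteroid kinase-like family were higher, 6 of them by 2-fold or more, with a median of 0.87, or 0.65 with dim values set to the floor. Members were CG10560 (at least 2.86-fold higher), CG10514 (1.71) and CG31370 (1.33). Runs of 7 genes there were matched in height in 160 and 232 of 1000 permuted gene orders, and in 623 and 298 with dim values set to the floor.

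The marker lists of neighbouring tissues moved in opposite directions after L. plantarum. Uro and other tubule genes were higher, while salivary gland genes, fat body genes and the cuticle genes Lcp1 and Lcp4 were lower. Tubule tissue carried in the L. plantarum pool may account for the first and remains open, since a second tubule list of 8 genes had a median of 0.28 at the 97.1 percentile, just inside the random range (0.26 and the 94.9 percentile with dim values set to the floor), and its members split, with the 3 that were below the floor with PBS higher (NaPi-T at least 1.78-fold, Oatp58Db at least 1.34-fold, Oatp58Dc from 38.9 to 78.2), Drip (0.48) higher, Picot (0.09) and tsh (0.01) near 0, and CG7881 (−0.18) and ClC-a (−0.39) lower. Fat body tissue in the PBS pool remains open, since 2 of the 4 larval serum protein genes were lower by 0.5 or more, Lsp2 (intensities 8147 and 3505) and Lsp1beta (4993 and 3329), while Lsp1gamma (−0.01) and Lsp1alpha (0.23) were not. A later larval stage in the PBS pool, which would bring glue proteins, also remains open, because the ecdysone response list lay at the 19.3 percentile with a median of −0.12, which turned to 0.02 (54.5 percentile) without a floor. Members of that list split, with 6 lower, among them br (−0.78) and EcR (−0.38), and 5 higher, up to Kr-h1 (0.32), so its median could not decide. Salivary gland tissue itself was not tested, and Sgs3, which lies in the same gene cluster as Sgs7 and Sgs8, had intensities of only 52.6 and 38.6, while 6 of the 10 salivary markers, among them Sgs1 (12.6 and 10.6) and Sgs4 (26.0 and 17.1), were below the floor in both pools.

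The IMD pathway genes pirk, PGRP-LF and PGRP-SC1b were higher by 2-fold or more, as was the antimicrobial peptide AttD (at least 4.70-fold). Among the other peptides DptA was higher (0.89), while Drsl3, Mtk and DptB were lower. Whether array noise of single genes gave the IMD list remains open. Only 0.18% of matched random lists held as many genes past 2-fold, but this became 6.66% after multiplication by the 37 lists examined. Random lists come from the same arrays and do not measure array noise, which 1 array per group cannot show. Tubule RNA in the L. plantarum pool as a source of pirk transcripts was not tested. A response to L. plantarum, whose peptidoglycan is of the type that IMD receptors bind, is the biological candidate. With 1 array per group it stays untested.

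Small nucleolar RNA genes were lower in 168 of 175 cases, 19 of them by 2-fold or more (14 with dim values set to the floor), with a median of −0.53 (−0.47 with dim values set to the floor), below every random list drawn. A lower yield of short RNA in the L. plantarum sample may be the cause, since all 15 small nuclear RNA genes were lower too, with a median of −0.52, and so were 3 of 3 distinct values among transfer RNA features. MicroRNA stem loops, also short, were not lower as a class, with 17 of 31 higher and a median of 0.02. Lower transcription of snoRNA host genes cannot be told apart, because 1 of the 2 noncoding host transcripts with values of their own was lower (Uhg4, −0.64) and the other higher (Uhg1, 0.95). Only noncoding host transcripts were examined, so other hosts of the 175 snoRNA genes were not checked. A response of snoRNA levels to L. plantarum was not tested.

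The highest run of 7 neighbouring genes lay on 2L from 10224664 to 10250479, from CG5708 to bsk, with a mean difference of 0.88. In 51 of 1000 permuted gene orders a run was as high, and in 44 of 1000 with dim values set to the floor (mean 0.85), so chance order was not excluded. The lowest runs held glue genes. Around Sgs5, where several genes were dim on 1 array, the mean was −1.25 (0 of 1000 orders as low), but −0.73 (390 of 1000) with dim values set to the floor, so this run stood apart only on values below the floor. Around Sgs7 and Sgs8 it was −1.13 (1 of 1000), or −1.08 (2 of 1000) with dim values set to the floor, and those 2 genes carried most of it.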
